A study of Homo sapiens with 9 samples.

How the data were processed

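Chromatin immunoprecipitation and sequencing with antibodies against DDX21 and CDK9 was applied to A375 cells under 3 treatments, per the labels. Per the labels' protocols, cells were treated for 24 h, A771726 was used at 25 µM, and libraries were amplified with 18 PCR cycles. The labels give 9 samples, 1 for each antibody and treatment and 1 input per treatment. A peak list was read for 6 of them, and the 3 inputs were not used here. Samples were grouped by their titles.

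The tools Bowtie and MACS2 2.0 and the genome build hg19 are named per the submitters' processing notes. Their roles, order, parameters and the control used for each list are not given in the sources used here. Each list belongs to 1 library, so peaks were not called on pooled samples. Each deposited list gives a peak's position, its summit, a fold enrichment (a ratio to the local background at the summit), a −log10 p-value and a −log10 q-value, as the authors' peak caller wrote them. The deposited score equals 10 times −log10 q, rounded down, in all 27469 peaks of the 6 lists, and was not used further. The lowest −log10 q of every list lay just above 1.3, the −log10 of 0.05. Read totals per library are not given in the sources used here, so depth was only estimated, relative to DMSO, as described in the last paragraph.

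Coordinates are those of the deposited lists, written from 1. The gene table at hand is of GRCh38 and the peaks are of hg19, so regions are named by chromosome, start and end and no gene was assigned. For the same reason the intended share of peaks near transcription start sites and the intended counts over gene lists were not made. These analyses, the naming of regions, the comparisons between lists, the deciles and all alternatives but those listed next were chosen before the data were examined. The heights and their alternatives, the clusters over pooled lists, the split by CDK9 overlap and by chromosome, and the alternative that leaves out peaks at high background were chosen after.

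Regions were named by rank of −log10 q within a list, then by −log10 p, fold enrichment and position, leaving out the mitochondrial genome and unplaced contigs. For each antibody the rule took the top 10 DMSO peaks, the top 10 DMSO peaks without an A771726 peak and the top 5 A771726 peaks without a DMSO peak. Peaks of the rDNA contig were also to be described, and no list had any. Whether that contig was part of the alignment is not given, so binding at rDNA could not be examined. The top peaks of the A771726 lists, the clusters and the shared site on chromosome 1 were named after their values were seen.

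A peak was counted as shared when it overlapped a peak of the other list by at least 1 bp. Shares carry exact binomial (Clopper-Pearson) 95% intervals, which treat peaks as independent and cover counting error only. With 1 library per group no p-value was computed. Overlap of CDK9 with DDX21 was set beside 100 placements of the CDK9 peaks at random on their own chromosomes. Peaks of a DMSO list were split into 10 deciles of −log10 q, and the share kept in a subset was set beside 10000 random sets of DDX21 peaks with the same numbers per decile. A cluster was a run of at least 5 peaks of 1 list, or of the 3 lists of an antibody together, with gaps of at most 10 kb. Clusters over the 3 lists together were ranked by all their peaks, those with A771726 included. Alternatives were a −log10 q of at least 5, leaving out the mitochondrial genome and unplaced contigs, an overlap of at least 50% of the shorter peak, summits within 250 bp, the same number of top peaks from each list, peaks within 1 kb merged, and leaving out peaks at a background of 50 fragments or more.

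The number of fragments over each summit was worked out from the deposited values. Fold enrichment was taken as (pileup + 1)/(background + 1) and −log10 p as the upper tail of a Poisson distribution, and a whole-number pileup met both within 0.001 of −log10 p for 100% of peaks in every list, with a largest error of 0.000129. Height is the pileup divided by the lowest background of its list. That lowest background is proportional to tags times fragment length, and the shortest peak was taken as the fragment length, so their quotient gave tags relative to DMSO: 1.06 for DDX21 with A771726, 0.884 for DDX21 with nucleotides, and 1.14 and 1.05 for CDK9. The highest pileup was exactly 2 times the shortest peak in the lists other than CDK9 with A771726, which is the limit that 1 tag per position and strand would set. Median pileups per list were 62, 46 and 63 fragments for DDX21 and 23, 15 and 24 for CDK9 in DMSO, with A771726 and with nucleotides. Heights were compared at the peaks of the eighth decile of the DDX21 list with nucleotides that had a peak in all 3 lists, with order-statistic intervals of the median. On simulated data, the method recovered 100% of 1000 pileups drawn for each list, and the overlap step made 0 wrong calls over all peaks of each list. The simulated values were made with the same 2 formulas, and peaks were moved either slightly or far away. The simulation therefore checked the code, and not whether the peak caller used these formulas. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.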

Results

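DDX21 and CDK9 were mapped on chromatin of A375 cells, a human melanoma line, by chromatin immunoprecipitation and sequencing. DDX21 is a DEAD-box RNA helicase that is concentrated in the nucleolus. CDK9 is the kinase of P-TEFb, which phosphorylates RNA polymerase II and releases it from promoter-proximal pausing. Cells were exposed for 24 h to DMSO, to 25 µM A771726, or to 25 µM A771726 with added nucleotides. A771726 is the active metabolite of leflunomide and inhibits dihydroorotate dehydrogenase, an enzyme of pyrimidine synthesis. The design therefore asks where the 2 proteins sit on the genome, how their sites differ when pyrimidine synthesis is inhibited, and whether added nucleotides restore them.

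The series described 9 samples. A peak list was read for each of the 6 immunoprecipitated libraries, and the 3 input samples were not used here. Each antibody and treatment had 1 library, so no difference between treatments could be set against a replicate error. Shares of peaks are given with exact binomial (Clopper-Pearson) 95% intervals, which cover counting error only. Fold enrichment and −log10 q are the values the authors' peak caller gave each peak, and they describe and rank peaks within the list they come from, without a comparison of their size between lists.

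DDX21 peaks were fewer with A771726 and nearly as many as in DMSO when nucleotides were added. The list held 8321 peaks in DMSO, 4375 with A771726 and 7922 with A771726 and nucleotides. These peaks covered 2861110, 1199442 and 2947137 bp, with median widths of 307, 241 and 334 bp. CDK9 followed the same order with a larger difference, from 3462 peaks in DMSO to 290 with A771726 and 3099 with nucleotides. The CDK9 lists covered 831787, 39205 and 768838 bp, with median widths of 186, 96 and 186 bp. The shortest peak was 128 bp in the CDK9 DMSO list and 50 bp in the CDK9 A771726 list, so the smallest enriched stretch that was called differed between these libraries and their peak numbers are not on an equal footing.

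**Figure D1:**
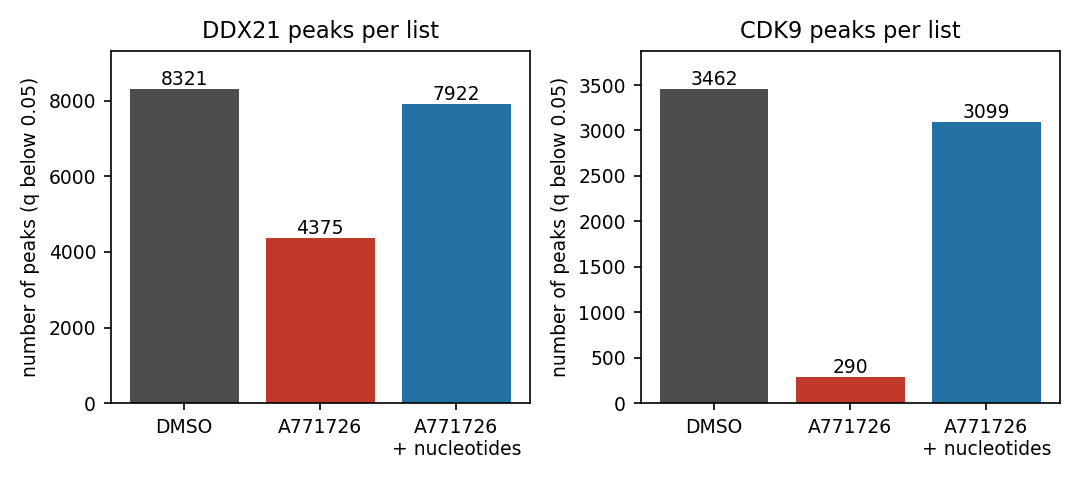
Number of peaks in each list at q below 0.05, with 1 library per bar, for DDX21 (left) and CDK9 (right). The lists with A771726 were the shortest of each antibody, with 4375 and 290 peaks.

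DDX21 and CDK9 peaks were spread differently over the genome in DMSO. Chromosome 19 held 9.75% (95% interval 9.12 to 10.4) of DDX21 peaks and 3.004% (2.46 to 3.63) of CDK9 peaks, and chromosome 12 held 4.84% (4.39 to 5.33) and 7.89% (7.01 to 8.83). CDK9 peaks also lay in groups: 16.4% (15.2 to 17.7) were in clusters of at least 5 peaks spaced by at most 10 kb, against 1.15% (0.935 to 1.41) of DDX21 peaks. No list held a peak on an unplaced contig. Whether such contigs were part of the alignment or the peak calling is not given, so nothing follows about binding there. The mitochondrial genome held 1 peak in each of the CDK9 lists from DMSO and from cells with nucleotides.

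The strongest DDX21 sites had a peak under all 3 treatments. The top DMSO peak lay on chromosome 14 from 82000013 to 82000671 (hg19, as for all coordinates), with a fold enrichment of 76.0. It was followed by chromosome 16 from 68482416 to 68482891, with 71.7, chromosome X from 48979903 to 48980424, with 69.8, and chromosome 4 from 2537877 to 2538450, with 74.1, in the order of −log10 q. All 10 of the top DMSO peaks overlapped a peak of the A771726 list and a peak of the list with nucleotides, and none overlapped a CDK9 peak under any treatment. A shared peak did not mean an equal height, and all 10 had a lower summit pileup with A771726 than in DMSO. At the top site the pileup was 243 fragments in DMSO, 106 with A771726 and 242 with nucleotides. The first peak of the A771726 list, on chromosome 1 from 2457475 to 2457860, overlapped the tenth of the DMSO list.

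About as many DDX21 sites of DMSO cells had a peak with A771726 as had none. Of 8321 DMSO peaks, 4253 overlapped an A771726 peak, a share of 51.1% (50.03 to 52.2). Almost all of the A771726 list was within the DMSO list, since 4345 of its 4375 peaks, or 99.3% (99.0 to 99.5), overlapped a DMSO peak. The DMSO peaks that were kept had a median fold enrichment of 18.8 in the DMSO list, and those that were not had 5.77. Keeping followed the rank in DMSO: 1.08% (0.495 to 2.04) of the lowest decile by −log10 q had an A771726 peak, 34.6% (31.4 to 38.0) of the fifth decile, 90.9% (88.7 to 92.7) of the seventh and all 832 of the highest. Peaks at sites shared by all 3 lists were narrower with A771726, with median widths of 399 bp in DMSO, 244 bp with A771726 and 436 bp with nucleotides. When each DDX21 list was reduced to its top 4375 peaks, 88.5% of DMSO peaks had an A771726 peak, so the share of 51.1% depends on list length.

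A few strong DDX21 sites went against this order. In the eighth decile, 827 of 832 DMSO peaks had an A771726 peak, and those without one were the top 5 of all DMSO peaks not kept. They lay on chromosome 1 from 101360269 to 101360865, with a fold enrichment of 24.8 in DMSO, chromosome 3 from 179065213 to 179065624, with 22.8, chromosome 11 from 33529608 to 33529875, with 31.7, chromosome 16 from 69364401 to 69364678, with 15.8, and chromosome X from 48814779 to 48815009, with 27.8. All 10 of the top DMSO peaks without an A771726 peak had a peak in the list with nucleotides. Only 30 A771726 peaks overlapped no DMSO peak. Of the top 5 of these, 3 lay within a short stretch of chromosome 8, from 43092765 to 43096057, another lay on chromosome 2 from 224903342 to 224903534, and the last on chromosome 7 from 133762214 to 133762333.

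With nucleotides, most DDX21 sites that were missing with A771726 alone had a peak. Of the 4068 DMSO peaks without an A771726 peak, 2936 overlapped a peak of the list with nucleotides, a share of 72.2% (70.8 to 73.5). Over the whole DMSO list the share was 86.3% (85.5 to 87.0), or 7180 peaks. The remainder came from the weakest DMSO peaks: 38.3% (35.0 to 41.7) of the lowest decile and 94.0% (92.2 to 95.5) of the fourth decile were found with nucleotides, and all peaks of the sixth decile and above. Sites kept with A771726 but absent with nucleotides numbered 9.

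**Figure D2:**
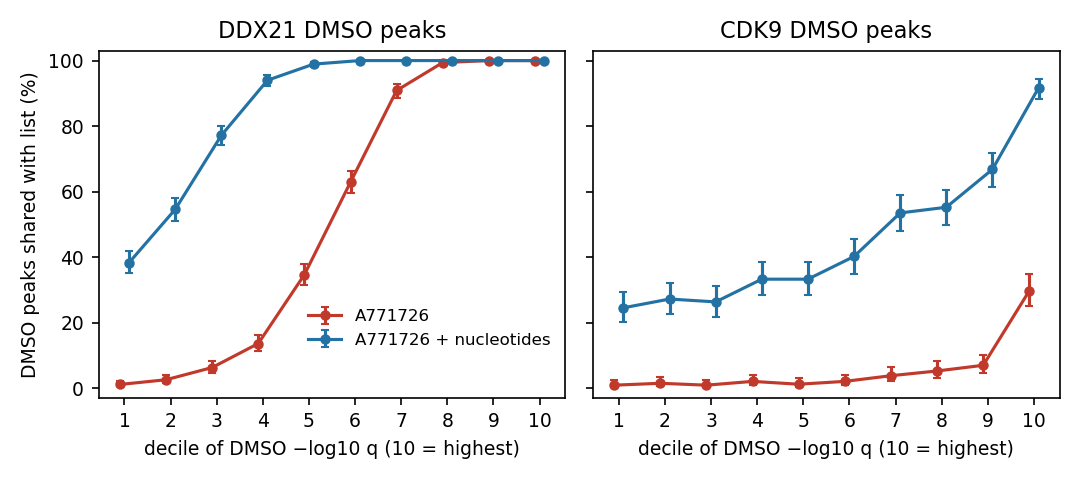
Percentage of DMSO peaks that overlap a peak of the list with A771726 (red) or with A771726 and nucleotides (blue), by decile of −log10 q in the DMSO list, with exact binomial 95% intervals. For DDX21 (left) the A771726 share rises from 1.08% to 100%, and for CDK9 (right) it reaches 29.7% in the highest decile.

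Few CDK9 sites of DMSO cells had a peak with A771726. Of 3462 DMSO peaks, 187 overlapped an A771726 peak, a share of 5.40% (4.67 to 6.21). The share was 0.865% (0.179 to 2.51) in the lowest decile of DMSO peaks and 29.7% (24.9 to 34.8) in the highest. Of the 290 CDK9 peaks with A771726, 225 lay on a DMSO peak, or 77.6% (72.3 to 82.3). When each list was reduced to its top 290 peaks, the share of DMSO peaks found with A771726 was 32.4%, so the value depends on list length.

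The strongest CDK9 peak with A771726 was on chromosome 6 from 52860358 to 52860801, with a fold enrichment of 21.8. It overlapped the second strongest DMSO peak, from 52860273 to 52860807. The first DMSO peak lay on chromosome 9 from 22158906 to 22159453, with a fold enrichment of 10.3, and was also first with nucleotides. Others in the top 10 were on chromosome 3 from 149293237 to 149294375, with 11.1, and on chromosome 11 from 65190174 to 65192404, with 9.62, and from 65266355 to 65267253, with 13.4. Of the top 10, 7 had an A771726 peak and 10 had a peak with nucleotides.

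Of the top 10 CDK9 DMSO peaks missing with A771726, 5 were close together on chromosome 1. The top DMSO peak without an A771726 peak lay there from 149831517 to 149832888, with a fold enrichment of 8.32, and 4 more of the top 10 started at 149811678, 149813259, 149822546 and 149824051. The others included chromosome 1 from 145382693 to 145383176, with 8.69, chromosome 6 from 26156464 to 26158095, with 15.5, the maximum of the DMSO list, chromosome 5 from 141736151 to 141737185, with 13.2, and chromosome 19 from 13947711 to 13948144, with 10.1. All 10 had a CDK9 peak with nucleotides. CDK9 peaks with A771726 and not in DMSO numbered 65, and 3 of the top 5 of them fell in the same stretch of chromosome 8 as the DDX21 peaks, starting at 43092889, 43093098 and 43094773. The other 2 were on chromosome 16 from 81995539 to 81995596 and on chromosome 7 from 20601319 to 20601391.

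With nucleotides, some of the CDK9 sites that were missing with A771726 alone had a peak. Of the 3275 CDK9 DMSO peaks without an A771726 peak, 1397 overlapped a peak with nucleotides, a share of 42.7% (41.0 to 44.4). Over all DMSO peaks the share was 45.2% (43.5 to 46.9), although the lists had similar lengths, and 1531 of the 3099 peaks with nucleotides lay on no DMSO peak. The share was 91.6% (88.2 to 94.3) in the highest decile of DMSO peaks, 66.8% (61.5 to 71.7) in the ninth, 55.2% (49.8 to 60.5) in the eighth and 24.5% (20.1 to 29.4) in the lowest.

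CDK9 peaks formed long clusters. Of the 20 with the most peaks, ranked with A771726 peaks included, 19 held fewer peaks with A771726 than in DMSO. The whole lists held 290 and 3462 peaks, so fewer in most clusters would follow from list length alone. Relative to list length these clusters held more, with 38.2 A771726 peaks per 100 in DMSO against 8.38 over the whole lists. Without the first cluster the ratio was 26.6 per 100. Within single lists, 31.4% (26.1 to 37.1) of CDK9 peaks with A771726, 16.4% (15.2 to 17.7) in DMSO and 17.8% (16.5 to 19.2) with nucleotides were in clusters of at least 5 peaks. Without the region of chromosome 2 from 224836877 to 224907328 these shares were 20.4% (15.6 to 25.9), 15.7% (14.5 to 17.0) and 17.2% (15.9 to 18.6), with overlapping intervals. For counts by region, clusters were taken over the 3 CDK9 lists together, a step chosen after the lists were seen. The cluster on chromosome 11 from 122007854 to 122073949 held 30 peaks in DMSO, 3 with A771726 and 25 with nucleotides. The cluster on chromosome X from 45607254 to 45634727 held 16, 1 and 22, that on chromosome 16 from 22018627 to 22038869 held 19, 1 and 11, and that on chromosome 12 from 24080857 to 24103492 held 14, 0 and 16. Clusters on chromosome 11 from 65264806 to 65275434, with 16, 8 and 12 peaks, and on chromosome 17 from 57906633 to 57920914, with 11, 8 and 10, differed less. The cluster with the most peaks, on chromosome 2 from 224836877 to 224907328, went the other way, with 31 peaks in DMSO, 40 with A771726 and 22 with nucleotides. Of these 20 clusters, 15 held no DDX21 peak in any list. The 67 clusters of the list with nucleotides, which neither of the lists compared had a part in choosing, held 126 peaks with A771726 for 484 in DMSO, or 26.0 per 100, against 8.38 per 100 over the whole lists. Without the region on chromosome 2 the ratio was 21.2 per 100. Shorter peaks can split 1 enriched stretch into several, so peak counts within a cluster also vary with peak width. Peaks in clusters were not matched to others on −log10 q. The share of CDK9 DMSO peaks with an A771726 peak was 0.865% in the lowest decile and 29.7% in the highest. These ratios therefore do not separate clustering from peak strength.

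**Figure D3:**
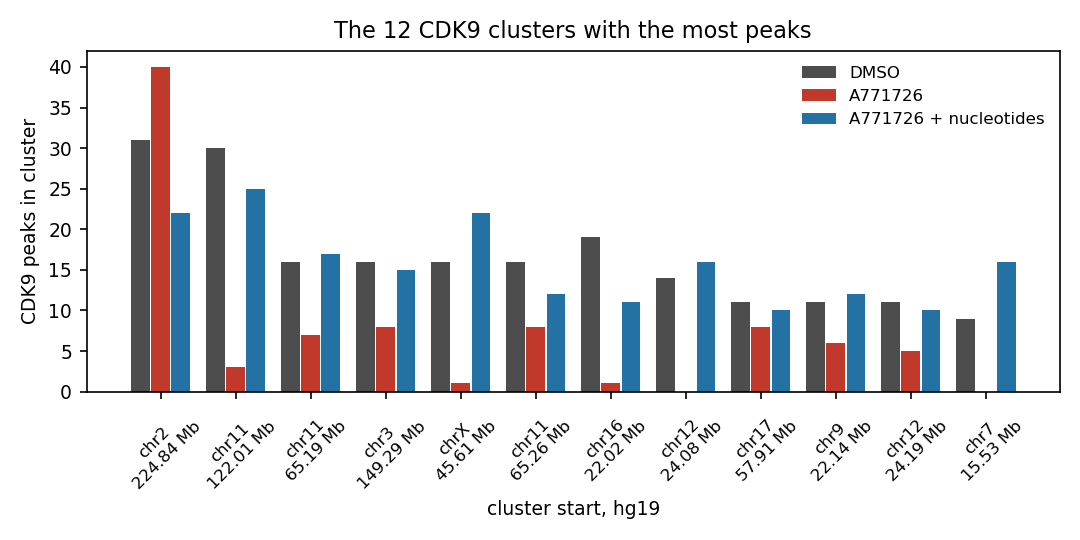
CDK9 peaks per treatment in each of the 12 clusters with the most peaks (peaks within 10 kb of the next, over the 3 lists together), named by chromosome and start. Peaks were fewer with A771726 than in DMSO in each but the first, on chromosome 2, which held 31, 40 and 22. The whole lists held 290 peaks with A771726 and 3462 in DMSO, so fewer peaks in most clusters would follow from list length alone.

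CDK9 and DDX21 shared a minority of their sites. In DMSO, 616 of 3462 CDK9 peaks overlapped a DDX21 peak, or 17.8% (16.5 to 19.1). With A771726 the share was 15.5% (11.5 to 20.2), or 45 of 290 peaks, and with nucleotides it was 13.6% (12.4 to 14.8), or 420 of 3099 peaks. Peaks placed at random on the same chromosome gave mean shares of 0.178%, 0.0690% and 0.169%, and at most 0.347%, 0.690% and 0.387% in 100 placements. From the side of DDX21, 7.38% (6.83 to 7.96) of peaks lay on a CDK9 peak in DMSO, 0.960% (0.693 to 1.295) with A771726 and 5.30% (4.82 to 5.82) with nucleotides. These shares are limited by the length of the CDK9 list, which held only 290 peaks with A771726. A shared site was the CDK9 peak on chromosome 1 from 149223655 to 149224240, which overlapped a DDX21 peak under all 3 treatments. The cluster on chromosome X from 114960357 to 115009600 held 17, 20 and 17 DDX21 peaks and 11, 1 and 5 CDK9 peaks in DMSO, with A771726 and with nucleotides. DDX21 peaks of this cluster had median backgrounds of 14.4 fragments in DMSO and 13.2 with A771726. The lowest backgrounds of these lists were 1.22 and 1.16. Median fold enrichments in the cluster were 6.38 and 3.58, against 10.1 and 9.31 over the whole lists. No result is therefore drawn from the counts of this cluster. Random placement ignores open chromatin. When both lists were reduced to as many top peaks as the CDK9 list held, the shares were 9.04% in DMSO, 0% with A771726 and 6.03% with nucleotides. These rest on the top 3462, 290 and 3099 peaks, so a much smaller part of the DDX21 list entered with A771726. They are therefore not comparable between treatments.

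DDX21 peaks on a CDK9 peak were kept with A771726 slightly more often than others. Of 614 such DMSO peaks, 377 had an A771726 peak, or 61.4% (57.4 to 65.3), against 50.3% (49.2 to 51.4) of the 7707 others. Random sets of DDX21 peaks with the same −log10 q deciles kept 58.5% on average, and 99.7% of 10000 such sets kept fewer than 377. Neither peak width nor the rank within a decile was matched, and kept DMSO peaks had a median width of 399 bp against 216 bp for the others. The sets also treat peaks of 1 library as independent, so the small excess may reflect width or strength. By chromosome, the share kept ran from 38.5% on chromosome X to 61.0% on chromosome 20, and matched random sets gave 37.8% and 60.3% there. Over all chromosomes compared, the shares with the lowest and highest percentiles among matched sets were 53.5% against 56.5% on chromosome 9, where at most 2.74% of sets kept as few, and 52.6% against 32.9% on chromosome Y, which had only 19 peaks and where at least 98.8% of sets kept fewer. A stretch of chromosome Y from 10033423 to 10037974 held 5 of these 19 peaks and 6 A771726 peaks. Their median backgrounds were 15.1 and 11.2 fragments, against lowest backgrounds of 1.22 and 1.16 in these lists, so no result is drawn for chromosome Y.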

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

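The alternatives for the DDX21 heights and those without peaks at a background of 50 fragments or more were chosen only after the results were seen. Of 90 alternatives, 63 of them planned, 58 stayed within the 95% interval of the value reported or, for a number of peaks, within 1.5 times it. A further 32 moved and 0 reversed. Leaving out the mitochondrial genome and unplaced contigs removed at most 1 peak from a list. That setting could hardly move any value, so its unmoved values say nothing about stability. A share or a number of peaks cannot change sign, so only a height could have reversed. With the same number of top peaks from each list, DMSO peaks with an A771726 peak were 88.5% for DDX21 and 32.4% for CDK9, those with a peak with nucleotides 93.1% and 51.0%, and those missing with A771726 but found with nucleotides 63.9% and 36.2%. CDK9 peaks on DDX21 peaks were then 9.04% in DMSO, 0% with A771726 and 6.03% with nucleotides, from the top 3462, 290 and 3099 peaks of both antibodies. At a −log10 q of at least 5, CDK9 had 2013 peaks in DMSO, 127 with A771726 and 1811 with nucleotides, the CDK9 share kept with A771726 was 4.57%, and CDK9 peaks on DDX21 peaks were 19.2% in DMSO and 22.8% with A771726. For DDX21 the shares were then 52.3% with A771726, 87.5% with nucleotides and 73.9% of the missing peaks. At this threshold the share of CDK9 peaks on DDX21 peaks was higher with A771726 than in DMSO. Over the lists as deposited the order was the other way, with 15.5% and 17.8%, and the 95% intervals overlapped in both settings. With an overlap of at least 50%, CDK9 shares were 41.5% with nucleotides and 38.9% of the missing peaks. With summits within 250 bp, DDX21 shares were 85.2% and 70.6%. Merging peaks within 1 kb left 193 CDK9 peaks with A771726. The log2 DDX21 height with A771726 against DMSO was −1.52 per tag, −1.44 with the background subtracted, and −1.47, −1.21 and −0.79 in deciles 7, 9 and 10. With nucleotides it was 0.080 per tag, 0.083 and 0.14 in deciles 9 and 10, and 0.022 at sites taken from the DMSO list. Except for the list-length and strict-threshold settings, where fewer peaks enter by construction, the cause was not tested. No paired analysis was possible because each group had 1 library and the labels carry no replicate numbers. The alternatives for windows around transcription start sites and for gene lists were not run. The median CDK9 pileup with A771726 was 15 fragments, at an estimated 1.14 times the tags of DMSO.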

Other observations

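All tests of explanations given here, and the choice of the heights and regions, were made only after the results were seen.

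DDX21 sites that kept a peak with A771726 were lower. At 787 of the 792 sites of the eighth decile of the list with nucleotides, all 3 lists had a peak, with median summit pileups of 134 fragments in DMSO, 49 with A771726 and 125 with nucleotides. Relative to the background of each library, the median log2 height with A771726 against DMSO was −1.38 (95% interval −1.41 to −1.35; SD over sites 0.34), a ratio of 0.385, and all 787 sites were lower. With nucleotides the median was 0.047 (0.032 to 0.061; SD 0.17). The intervals are over sites of 1 library per treatment. In the tenth decile the log2 height with A771726 was −0.79. It was also nearer to that of DMSO in deciles 2, 3 and 4, at −0.78, −1.06 and −1.19, and was −1.40 and −1.42 in deciles 5 and 6. Only 20, 52 and 142 sites of deciles 2, 3 and 4 had a peak in all 3 lists. Over the whole lists, 518 DMSO pileups lay within 10% of the limit of 2 times the shortest peak, against 61 with A771726.

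Some regions stood apart from the rest of the lists. A stretch of chromosome 8 from 43092765 to 43097145 held 0, 5 and 2 DDX21 peaks and 1, 4 and 5 CDK9 peaks in DMSO, with A771726 and with nucleotides. Its highest pileups with A771726 were 63 fragments for DDX21 and 57 for CDK9. These had fold enrichments of 4.64 and 5.30, against medians of 9.31 and 5.81 over the whole A771726 lists. Other peaks of the stretch had more, with highest fold enrichments with A771726 of 8.28 for DDX21 and 9.03 for CDK9. With nucleotides the highest were 7.32 and 16.4, and 16.4 was the maximum of that CDK9 list. The DDX21 list with nucleotides held 39 peaks on chromosome 16 from 46386880 to 46435530, where the other DDX21 lists held 0, and 20 peaks on chromosome 10 from 42380153 to 42400600, where DMSO held 1 and A771726 held 0. The median background there was 116 and 107 fragments and the median fold enrichment 1.55 and 1.53, against 9.80 over the whole list. At the CDK9 site on chromosome 6 from 52860358 to 52860801, the log2 height over background with A771726 against DMSO was 0.79, and 18 of the 187 shared sites were above it. Counted per tag instead, it was −0.56.

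The DDX21 list was shorter with A771726, and the sites it kept were lower. Fewer tags entering the peak calling were not the cause by the estimate made here, which gave the A771726 library 1.06 times the tags of the DMSO library. Sequenced totals, and whether tags were removed before peak calling, are not given. The shorter fragment length, 116 bp against 128 bp, could remove at most 24 fragments from a site under 1 tag per position and strand, and the median site of the eighth decile had 86.5 fragments fewer per tag. Whether 1 factor acted on every site stays open, since the SD over sites was 1.38 times the counting SD with A771726 and 0.943 times with nucleotides, but pileups are limited by a highest value and each treatment has 1 library. A lower yield of that immunoprecipitation and a lower occupancy by DDX21 under inhibited pyrimidine synthesis cannot be told apart with 1 library per antibody and treatment, so a loss of DDX21 from chromatin that nucleotides prevent stays a hypothesis.

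The fragment length of the CDK9 list with A771726, taken from its shortest peak, was 50 bp against 128 bp in DMSO, and this may account for part of its shortness. Tags entering the peak calling were not fewer, at an estimated 1.14 times those of DMSO. At the 187 shared sites the median log2 height was −0.10 (95% interval −0.15 to 0.02) over background and −1.46 per tag, where the ratio of fragment lengths alone would give −1.36, but over background it was −0.27 (−0.39 to −0.14) at the 100 sites of the tenth decile of the list with nucleotides that were in all 3 lists, with 75 of them lower. If every DMSO pileup and background shrank in proportion to fragment length and tags, 966 of the 3462 DMSO peaks would still pass the lowest −log10 p of the A771726 list, and 139 of these 966 were in it, while at the lowest share of tags that the shorter length can leave 10 would pass and 8 of them were in it. Proportional shrinkage is an assumption and the shared sites were selected by being called. With 1 library, the fragment length, a lower yield of that immunoprecipitation and a lower occupancy by CDK9 cannot be told apart here.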
